A study of Mus musculus with 16 samples.

How the data were processed

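Messenger RNA was sequenced from mouse bone marrow-derived macrophages in 16 libraries, 4 per group, with each of 4 mice giving 1 library to each group. Libraries were made by poly(A) capture, per the labels' protocols. Reads were aligned with HISAT2 to GRCm39 (mm39), per the submitters' processing notes. The aligner version, the counting tool, strandedness and the annotation release are not given in the sources used here. The deposited count table held raw counts per gene for all 16 libraries, with gene identifiers, names, coordinates, lengths and biotypes per the file headers. The deposited FPKM values (fragments per kilobase, scaled to library size) were scaled by the authors, per the file headers and the values: in each library, count over gene length divided by FPKM was constant, and these constants were proportional to median-of-ratios effective library sizes. FPKM values were used only as an alternative unit.

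Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Of 56748 genes in the table, 13438 passed filterByExpr on the 4 groups (minimum count 10, minimum total 15), of which 11587 were protein coding by the biotype in the table. Libraries were scaled with TMM factors (0.738 to 1.26). A robust edgeR quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, and 5 contrasts were tested with a threshold of 0.05 on the Benjamini-Hochberg adjusted p: LPS versus DMSO, SR9009 versus DMSO, SR9009 and LPS versus LPS, SR9009 and LPS versus SR9009, and the interaction, which is the SR9009 effect with LPS minus that without. The common biological coefficient of variation was 0.377. CPM values were computed with the TMM-scaled library sizes, and errors are SD over 4 libraries. Each SE is the size of the log2 fold change divided by the square root of its F statistic. It was derived from the test and not estimated separately. Where a group held 1 to 3 counts, the ratio of summed counts, each divided by the summed TMM-scaled library sizes of its group, is given with its exact 95% interval. Where it held none, a floor of 3 counts over the group was used with the same scaling. List medians with such members were the same with these members set to their bound.

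The 24 gene lists and 9 lists of cell type markers were written from general knowledge, and these lists, the tests, the thresholds and the rule for naming genes were fixed before the data were examined. Lists were tested with limma camera on voom values (preset correlation 0.01, adjusted over all lists of a comparison), and again with an estimated correlation, with fry and with the replicate block. Lists with fewer than 3 tested members got no list test. Genes were named by rule: for each of the 3 main comparisons, the 6 largest positive and 6 largest negative log2 fold changes among called protein-coding genes with a mean of at least 5 CPM and the same direction in 4 of 4 mice. Also named were called members of the plasminogen and clock lists; up to 4 members of each other list with the smallest p, and treatment check genes. For the interaction the 5 largest in each direction were taken. Some genes that the rule names are not reported here.

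SR9009 effects with and without LPS were compared by correlation across genes and by genes called in both. Genes called in LPS versus DMSO with an absolute log2 fold change of at least 1 were followed in SR9009 and LPS versus LPS. Because these comparisons share the LPS libraries, the same measure was taken in 20 sets of simulated counts with no SR9009 effect, and with the LPS-responsive genes and the SR9009 effect taken from different mice. All 35 splits of the 8 libraries of each comparison were refitted.

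The alternatives set in advance were RLE and upper-quartile scaling, no filter (26596 genes) and a stricter filter (1 CPM in 4 libraries), DESeq2, limma-voom, limma on log2 FPKM with a pseudocount of 1 or 0.1, mouse number as a factor (the replicate block) with and without a gene length correction, a fit of the compared groups alone, and leaving out each mouse and each library in turn. Alternatives added after seeing the data were a correction for transcript GC content, leaving out the SR9009 library of mouse 1 together with the replicate block or in the list tests and overlaps, the replicate block with an estimated correlation, and fits of mice 1 and 2 or mice 3 and 4 alone. GC content came from the longest transcript of each gene identifier in GENCODE M21, used for sequence composition only, and was found for 13252 of the tested genes (98.6%). Length and GC corrections used a loess trend with a span of 0.5.

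The fitting steps were tested on simulated data with known changes. The changed genes were taken from those with a mean of at least 1 CPM, and counts were drawn independently. For SR9009 versus DMSO, with 13438 genes and 100 genes changed by each size, 79 changed by 2 on the log2 scale and 11 changed by 1 were recovered, with 3 unchanged genes called. For SR9009 and LPS versus LPS the numbers were 78, 10 and 3.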

Results

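Bone marrow-derived macrophages grown from 4 male C57BL6 mice were profiled by RNA sequencing in 4 groups of 4 libraries: vehicle (DMSO), LPS, SR9009, and SR9009 followed by LPS. Lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4, was given at 100 ng/mL for 6 hours. SR9009, a synthetic agonist of the clock repressors REV-ERBα and REV-ERBβ (encoded by Nr1d1 and Nr1d2), was given at 10 µM for 16 hours. The labels of the LPS group name LPS alone and do not state whether DMSO was given overnight. If it was not, the comparisons of LPS with DMSO and of SR9009 and LPS with LPS, their sets of LPS-responsive genes and the interaction include a difference in vehicle. The series title places the work in the control of the fibrinolytic activity of innate immune cells by the clock. Total counts ran from 12616442 to 24214863 per library, and 13298 to 18947 genes had at least 1 count. The SR9009 library of mouse 1 had both the lowest total and the lowest number of genes; the next lowest number was 16419. Across the 16 libraries, the first principal component held 52.1% of the variance and the second 25.4%. On the second, the SR9009 library of mouse 1 scored 215.3 and all others lay between −48.6 and 32.1, so it mainly set that library apart. Deviations from the group means correlated positively across genes for all 24 pairs of libraries that shared a mouse number (r from 0.0825 to 0.495). Genes are not independent replicates. The 72 pairs from different mice had a median r of −0.0791 but reached 0.452, so positive values were not limited to the same mouse. The total count of genes of each comparison is given below also with mouse number in the model. Counts of list members and values of single genes come from the fit without it, except where stated.

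**Figure D1:**
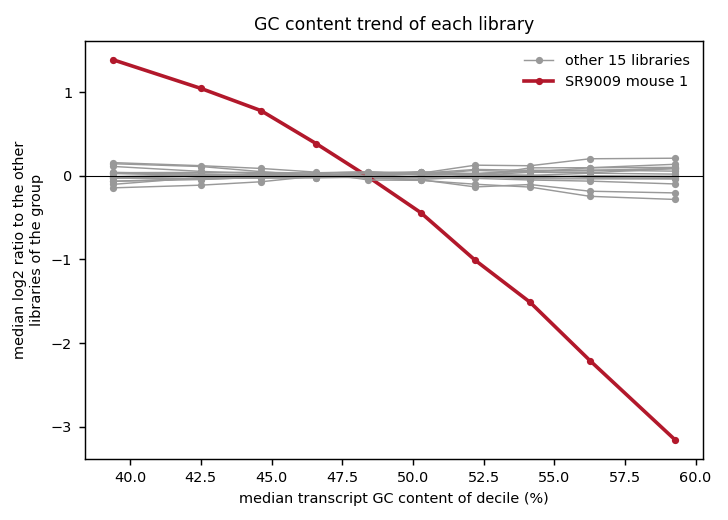
Median log2 ratio of each library to the other libraries of its group in deciles of transcript GC content (percent). The SR9009 library of mouse 1 was left out of the reference for the other SR9009 libraries. The SR9009 library of mouse 1 falls with GC content (Spearman −0.712 across genes), against at most 0.193 in size in the other 15 libraries.

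The comparison of LPS with DMSO asks how the macrophages responded to LPS without SR9009. Serpinb2, which encodes an inhibitor of plasminogen activators (ENSMUSG00000062345, chromosome 1, 107439153 to 107463208, GRCm39), rose from 0.547 ± 0.699 to 169 ± 28.8 CPM (counts scaled to library size; SD, n = 4; log2 8.30, SE 1.01, edgeR adjusted p = 1.04e-05). Plau, the urokinase-type activator gene, fell by 2.09 on the log2 scale (SE 0.43, adjusted p = 0.00109), from 30.9 ± 9.49 to 7.24 ± 2.57 CPM. Transcripts on the activating side rose as well: the tissue-type activator gene Plat (log2 5.34, SE 0.82, but only 2.12 ± 0.773 CPM with LPS), the urokinase receptor gene Plaur (log2 2.44, SE 0.59), and Anxa2 and S100a10, whose products form a plasminogen receptor (log2 1.14 and 0.56). Serpinb6a and Serpinb8, which encode intracellular protease inhibitors, fell by 0.98 and 1.04.

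**Figure D2:**
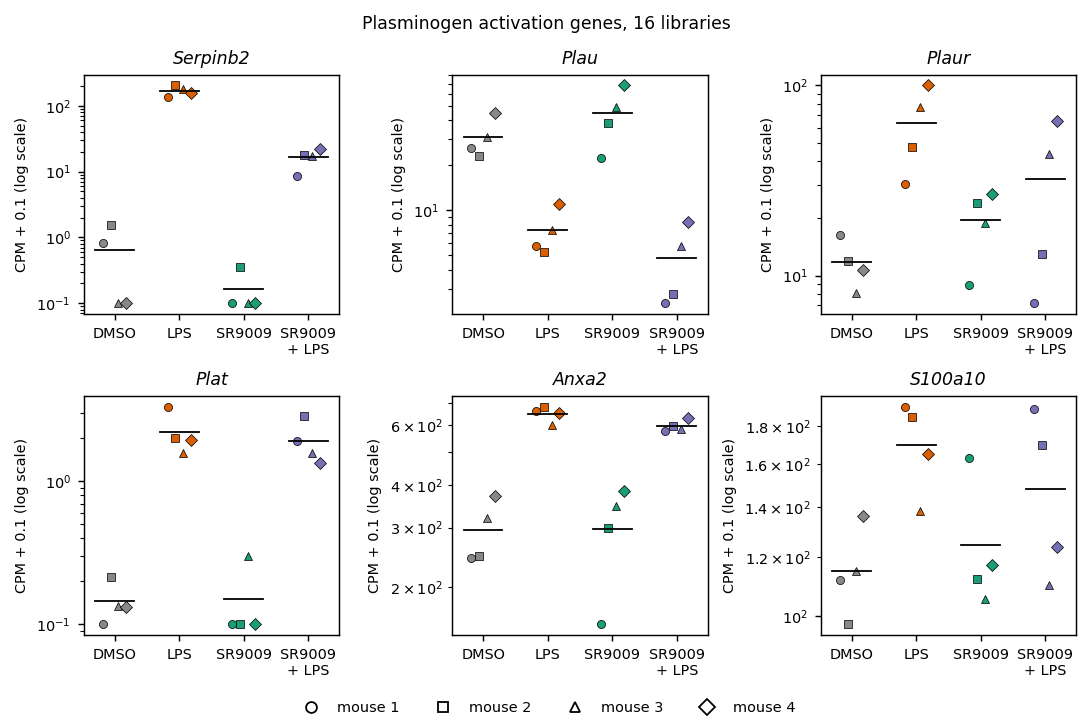
Level of 6 plasminogen activation genes in each of the 16 libraries (CPM plus 0.1, log scale) by treatment group; symbols mark the mouse and the line the group mean. Serpinb2 averaged 169 CPM with LPS and 16.4 CPM with SR9009 and LPS.

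Of the 16 tested members of the plasminogen activation and fibrinolysis list, 6 were higher and 3 lower with LPS, and the counts adjusted over the list alone were also 6 and 3. The list as a whole did not pass (median log2 0.75, camera adjusted p = 0.0668, and adjusted p = 0.261 with an estimated correlation). Inflammatory genes were higher: 31 of 32 tested cytokines and mediators rose (31 adjusted over the list alone; median log2 6.86, camera adjusted p = 2.06e-19, adjusted p = 0.0293 with an estimated correlation). Nos2, the inducible nitric oxide synthase gene, rose from 0.580 ± 0.463 to 2684 ± 1480.0 CPM, and Tnf from 12.5 ± 3.90 to 924 ± 163 CPM. Il6 had 2 counts over the 4 DMSO libraries and 1886 with LPS, a ratio of 1844 after scaling to library size (95% counting interval 510 to 15239). Other large increases were in Lipg (endothelial lipase, log2 12.27), Lcn2 (lipocalin 2, 11.49) and Il12b (10.59). Edn1 (endothelin 1) had a ratio of 5906 over 3 DMSO counts (interval 2020.3 to 28644). Shisa3, at 0 in all DMSO libraries, was at least 1089-fold higher, from a floor of 3 counts over the group. These intervals and floors cover counting error only. Interferon-stimulated genes rose in 42 of 43 cases (42 adjusted over the list alone; median log2 3.23, camera adjusted p = 8.96e-26, but adjusted p = 0.181 with an estimated correlation), with Gbp2 at 5.77 and Cmpk2 at 5.23. Of 33 negative regulators of Toll-like receptor signalling, 29 rose and 1 fell (29 and 1 adjusted over the list alone, median 2.72, camera adjusted p = 5.8e-18, adjusted p = 0.0293 with an estimated correlation), among them Il1rn, the interleukin 1 receptor antagonist gene (log2 8.07). With the replicate block (mouse number as a factor) added to the estimated correlation, a setting chosen after seeing the data, 0 lists passed in this comparison. The calls of this list and of the inflammatory list thus ended there.

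Among 21 clock genes, 8 fell and 2 rose with LPS (8 and 2 adjusted over the list alone; median −0.29, camera adjusted p = 0.25 and adjusted p = 0.495 with an estimated correlation). The output genes Dbp, Tef and Per3 fell by 3.17, 3.00 and 3.07, Rora by 1.46, Nr1d2 by 1.37, Per2 by 0.94, Csnk1e by 0.88 and Npas2 by 3.38. Npas2 had 47 against 2 counts, a ratio of 12.0 after scaling to library size (interval 3.15 to 102). Nfil3 (2.51) and Ciart (2.09) rose. Nr1d1 (log2 −0.01, adjusted p = 0.994) and Arntl, which encodes BMAL1 (−0.29, adjusted p = 0.589), did not pass. Glycolysis genes rose in 15 of 26 cases and fell in 2 (median 1.58, camera adjusted p = 0.000742, adjusted p = 0.495 with an estimated correlation; 15 and 2 adjusted over the list alone), with Pfkfb3 at 4.84 and Hk2 at 2.50. Cell cycle and DNA replication genes fell in 25 of 47 cases and rose in 3 (28 and 3 adjusted over the list alone; median −1.21, camera adjusted p = 0.00223, adjusted p = 0.73 with an estimated correlation), with Mcm7 at −2.70 and Prim1 at −2.65. Ccnd2 rose by 5.99. Cholesterol synthesis genes rose in 11 of 24 cases and fell in 1 (11 and 1 adjusted over the list alone; median 0.73, camera adjusted p = 0.0258, adjusted p = 0.577 with an estimated correlation), and without the SR9009 library of mouse 1 the list did not pass (adjusted p = 0.0695). The largest decreases were in Rasgrp3 (−8.99), Cd28 (−7.53), the chemokine receptor gene Cxcr4 (−7.14, from 267 ± 24.9 to 1.89 ± 0.377 CPM), Slco2b1 (−6.82), Gpr34 (−6.77) and St6gal1 (−6.13). In all, 2611 genes were higher and 2741 lower of 13438 tested, and 2867 and 3180 with the replicate block (mouse number as a factor). Upper-quartile scaling moved the median log2 fold change of all genes from −0.08 to −0.28 and gave 2126 higher and 3459 lower, so the balance between directions depends on the scaling. Without mouse 2, 3 or 4 the counts were 1830 and 1765, 1831 and 1717, and 1817 and 1689. Without the SR9009 library of mouse 1, with filter, scaling and spread computed anew, they were 3658 and 4177.

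The comparison of SR9009 with DMSO asks what the REV-ERB agonist did without LPS. Interferon-stimulated genes were lower: 25 of 43 fell and 0 rose (41 adjusted over the list alone; median log2 −1.87). Cmpk2, a mitochondrial nucleotide kinase gene, fell from 117 ± 52.9 to 17.2 ± 5.50 CPM (log2 −2.76, SE 0.39, edgeR adjusted p = 0.00414) and Zbp1, a nucleic acid sensor gene, from 77.3 ± 42.5 to 12.8 ± 4.42 CPM (−2.59, SE 0.34, adjusted p = 0.00414), in 4 of 4 mice each. The chemokine genes Cxcl10 (−3.67) and Ccl12 (−3.31), Ifit1bl1 (−5.46), Ifi208 (−4.09), Iigp1 (−3.75) and Ifit3b (−3.55) were the largest decreases among protein-coding genes with a mean of at least 5 CPM and the same direction in 4 of 4 mice. The rankings of other comparisons have the same limits. Ifit3b has a near-identical paralog, Ifit3, from which reads were not told apart here. Camera gave adjusted p = 1.35e-46 for the list, and adjusted p = 0.0934 with an estimated correlation. Without the SR9009 library of mouse 1 the list median was −1.74.

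Targets of NRF2, the regulator of the antioxidant response, were higher: 8 of 27 rose and 0 fell (13 adjusted over the list alone; median log2 0.88, camera adjusted p = 7.16e-13, adjusted p = 0.184 with an estimated correlation). Gsta3, a glutathione transferase gene (ENSMUSG00000025934, chromosome 1, 21310813 to 21335885), rose from 3.53 ± 1.12 to 33.4 ± 6.78 CPM (log2 3.24, SE 0.28, adjusted p = 5.77e-05), Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, by 2.33, catalase (Cat) by 1.79 and Prdx6 by 1.00. Of 24 genes of cholesterol synthesis and SREBP2 control, 1 rose over all genes and 15 rose adjusted over the list alone (median 0.79, camera adjusted p = 7.92e-11, adjusted p = 0.184 with an estimated correlation). Scd1 (1.88) and Scd2 (1.46), both fatty acid desaturase genes, the lipid carriers Fabp4 (2.43) and Fabp5 (1.09), the scavenger receptor gene Cd36 (1.28), Ednrb (2.56), Sema3c (2.39), Gadd45a (2.02), Mmp12 (1.87) and Mthfd2 (1.49) also rose. Il10 (−2.61), Cx3cr1 (−1.86), the Fc receptor gene Fcgr1 (−1.74), Tlr2 (−1.26), and Ciita (−3.47) and Cd74 (−2.17) of class II antigen presentation fell.

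Of 32 inflammatory mediators, 3 were lower with SR9009 than with DMSO (5 adjusted over the list alone; median −0.61, camera adjusted p = 0.00788, adjusted p = 0.521 with an estimated correlation). Fatty acid synthesis had 2 of 22 higher (4 adjusted over the list alone; median 0.22, camera adjusted p = 0.00816, adjusted p = 0.438 with an estimated correlation). None of 33 negative regulators of Toll-like receptor signalling passed with edgeR, DESeq2 or limma-voom, and 1 was higher and 4 lower at an unadjusted p under 0.05 in edgeR (0 adjusted over the list alone). Their median was −0.34 (camera adjusted p = 0.0153, adjusted p = 0.521 with an estimated correlation). None of 26 glycolysis genes passed with edgeR or limma-voom and 1 did with DESeq2; 5 were higher at an unadjusted p under 0.05 (1 adjusted over the list alone). The glycolysis list did not pass (median 0.28, camera adjusted p = 0.162) but did without the SR9009 library of mouse 1 (adjusted p = 2.44e-09). With that library left out, the replicate block and an estimated correlation, the glycolysis list did not pass (adjusted p = 0.154).

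None of the 16 tested plasminogen genes passed in SR9009 against DMSO with edgeR, DESeq2 or limma-voom; at an unadjusted p under 0.05, 2 were higher and 1 lower in edgeR (median log2 0.20, camera adjusted p = 0.453, adjusted p = 0.521 with an estimated correlation; 0 adjusted over the list alone). Plau was at 44.3 ± 19.2 CPM against 30.9 ± 9.49 (log2 0.52, adjusted p = 0.656). Of 21 clock genes, Bhlhe40 alone passed (log2 1.38, SE 0.30, adjusted p = 0.0426; 1 adjusted over the list alone; past the threshold in 15 of 37 other settings, with adjusted p up to 0.528), and the list had a median of 0.31 (camera adjusted p = 0.0153, adjusted p = 0.184 with an estimated correlation). Arntl, a gene repressed by REV-ERB in textbook accounts, had a log2 fold change of 0.33 (adjusted p = 0.775), from 15.3 ± 2.53 to 19.3 ± 11.3 CPM, with 36.2 CPM in the mouse 1 library and 12.8 to 15.1 CPM in the other 3 SR9009 libraries. The sign of Arntl turned without the SR9009 library of mouse 1 (−0.20, adjusted p = 0.997). Over all genes, 42 were higher and 76 lower; with the replicate block 69 and 129. Without mouse 1 the counts were 76 and 118. Without mouse 2, 3 or 4 they fell to 4 and 5, 1 and 17, and 1 and 0 (1030 genes at an unadjusted p under 0.05 in the last case). Without the SR9009 library of mouse 1 they were 95 and 147. A fit of the DMSO and SR9009 groups alone gave 2 and 2 (863 genes at an unadjusted p under 0.05), and 4 of the 118 calls remained, with 3 of 33 named genes. Of 33 named genes that passed, 0 passed with mice 1 and 2 alone and 31 with mice 3 and 4 alone.

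**Figure D3:**
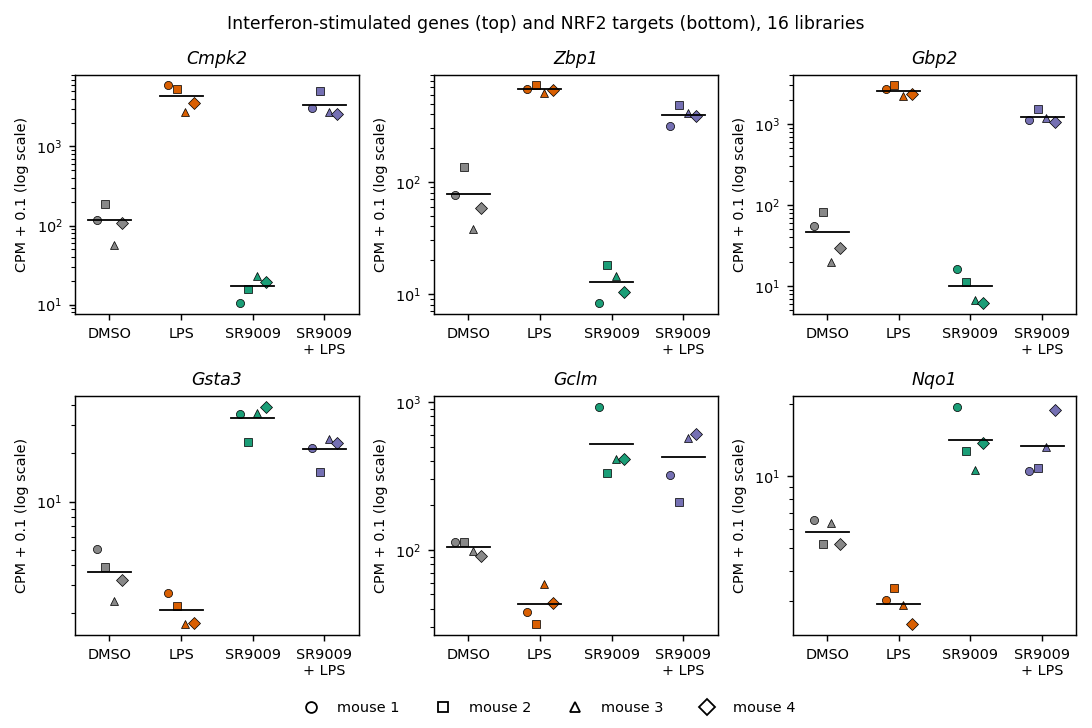
Level of 3 interferon-stimulated genes and 3 NRF2 targets in each of the 16 libraries (CPM plus 0.1, log scale) by treatment group; symbols mark the mouse and the line the group mean. Cmpk2 averaged 117 CPM in DMSO and 17.2 CPM with SR9009, and Gsta3 averaged 3.53 and 33.4 CPM.

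The comparison of SR9009 and LPS with LPS asks whether the agonist altered the response to LPS. Serpinb2 fell from 169 ± 28.8 to 16.4 ± 5.71 CPM (log2 −3.36, SE 0.78, n = 4, edgeR adjusted p = 0.0396), in 4 of 4 mice. Plaur (log2 −0.99, adjusted p = 0.485), Plau (−0.62, adjusted p = 0.584) and Plat (−0.21, adjusted p = 0.945) did not pass. Of 16 tested plasminogen genes, 0 rose and 2 fell (2 adjusted over the list alone), with a list median of −0.20 (camera adjusted p = 0.0347, and adjusted p = 0.105 with an estimated correlation). The replicate block gave adjusted p = 0.0278 for Serpinb2. Its estimate ranged over 37 other settings from −3.69 to −3.06, with 21 settings past the threshold. The call ended without mouse 2, 3 or 4 (adjusted p up to 0.288) and with DESeq2. Without mouse 1, or without the SR9009 library of mouse 1 alone, the list did not pass (camera adjusted p = 0.125 in each case).

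NRF2 targets were again higher, 10 of 27 with 0 lower (17 adjusted over the list alone; median log2 1.25, camera adjusted p = 4.37e-16, adjusted p = 0.105 with an estimated correlation). Gsta3 rose from 1.99 ± 0.462 to 21.1 ± 4.14 CPM (log2 3.41, SE 0.29, adjusted p = 2.29e-05), Gclm by 3.32, the cystine transporter gene Slc7a11 by 3.18, Nqo1 by 2.24 and Prdx1 by 2.06. Slc40a1, which encodes the iron exporter ferroportin, had the largest increase (4.14), followed outside that list by Ednrb (3.15) and Slc22a4 (2.94). In cholesterol synthesis, 2 of 24 genes rose, Dhcr7 (1.71) and Lss (1.08), and 14 rose adjusted over the list alone (median 0.91, camera adjusted p = 2.25e-14, adjusted p = 0.105 with an estimated correlation). Fatty acid synthesis had 5 higher and 1 lower of 22 (11 and 1 adjusted over the list alone; median 0.73, camera adjusted p = 2.42e-06, adjusted p = 0.105 with an estimated correlation), with Scd1 at 1.88, Scd2 at 1.59 and Fads1 at 1.26. Dgat2, of triglyceride synthesis, fell by 1.77. With the replicate block, 6 cholesterol synthesis genes rose and 0 fell, and 8 fatty acid synthesis genes rose and 1 fell. Lysosomal lipase (Lipa, 1.40) and Aldoc (1.09) rose.

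Genes that LPS had raised were among the largest decreases: Il1rn fell from 2295 ± 702 to 264 ± 72.0 CPM (log2 −3.12, SE 0.33, adjusted p = 0.000253), the collagenase gene Mmp13 by 3.15, Lipg by 3.13, Tnc by 3.27 and Gm5150 by 3.30. Negative regulators of Toll-like receptor signalling had 5 of 33 lower (9 adjusted over the list alone; median −0.41, camera adjusted p = 4.25e-09, adjusted p = 0.105 with an estimated correlation), including Il4ra (−2.62), Dusp2 (−1.84) and Tnip3 (−1.57). Inflammatory mediators had 1 of 32 lower, Ccl12 (−2.64), with 4 lower and 1 higher adjusted over the list alone (median −0.60, camera adjusted p = 7.85e-08, adjusted p = 0.16 with an estimated correlation). The replicate block called 4 of these mediators lower and 0 higher. Tnf (log2 −0.23, adjusted p = 0.946), Il6 (−0.52, adjusted p = 0.828), Nos2 (−0.93, adjusted p = 0.447) and Acod1 (−0.15, adjusted p = 0.948) did not pass without it. The Fc receptor genes Fcgr4 (−1.90) and Fcgr3 (−1.28), Maf (−1.16), Mmp25 (−2.06) and Pfkfb3 (−1.56) fell. So did Csf3r, on the neutrophil marker list (−1.68), and the histidine decarboxylase gene Hdc, on the mast cell marker list (−2.19). None of 43 interferon-stimulated genes passed with edgeR or limma-voom and 1 did with DESeq2; 8 were lower at an unadjusted p under 0.05 (median −0.26, camera adjusted p = 0.000161, adjusted p = 0.543 with an estimated correlation; 0 adjusted over the list alone). No clock gene of 21 passed with edgeR, 4 were higher at an unadjusted p under 0.05, 1 passed with DESeq2 and 0 with limma-voom (1 higher adjusted over the list alone). Arntl was at 0.55 (adjusted p = 0.61) and Nr1d1 at −0.58 (adjusted p = 0.651).

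In all, 142 genes were higher and 99 lower with SR9009 and LPS than with LPS, and 296 and 239 with the replicate block. Limma-voom gave 90 and 138, so the balance of directions depends on the tool. Without mouse 1 the counts were 570 and 393. Without mouse 2, 3 or 4 they were 21 and 5, 5 and 4, and 2 and 3. Without the SR9009 library of mouse 1 they were 912 and 654. With mice 1 and 2 alone they were 0 and 0 (1353 genes at an unadjusted p under 0.05) against 2063 and 2077 with mice 3 and 4 alone.

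LPS on top of SR9009, compared with SR9009 alone, gave 1944 genes higher and 2126 lower (2207 and 2362 with the replicate block). Inflammatory mediators rose in 32 of 32 cases (32 adjusted over the list alone; median log2 6.84, camera adjusted p = 4.01e-21, adjusted p = 0.0214 with an estimated correlation) and interferon-stimulated genes in 43 of 43 (43 adjusted over the list alone; median 4.95, camera adjusted p = 1.61e-40, adjusted p = 0.0487 with an estimated correlation). Tnf rose by 6.83, Nos2 by 12.61 and Acod1 by 6.44. Nr1d2 fell by 1.63, and without the SR9009 library of mouse 1 it fell by 0.98. Upper-quartile scaling gave 1706 higher and 2779 lower and RLE scaling 2057 and 1919, so the balance between directions depends on the scaling here too. Without mouse 2, 3 or 4 the counts of genes were 1307 and 1123, 1345 and 1181, and 1360 and 1170. Without mouse 1 they were 3040 and 2797, and without the SR9009 library of mouse 1 they were 3103 and 2832.

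The test of the difference between the SR9009 effects with and without LPS called 1 gene, Gm5150 (ENSMUSG00000078780, chromosome 3, 16001034 to 16060601), with a double difference of −2.72 (SE 0.36, edgeR adjusted p = 0.0168, 4 of 4 mice). It rose from 3.04 ± 0.381 to 23.8 ± 6.40 CPM with LPS and stood at 2.04 ± 0.263 CPM with SR9009 and 2.41 ± 0.560 CPM with both. In edgeR, 0 genes were higher and 959 had an unadjusted p under 0.05. DESeq2 called 53 higher and 50 lower, limma-voom 0 and 0, and the replicate block 11 and 4. Among interferon-stimulated genes, DESeq2 called 13 higher, limma-voom 0 and the replicate block 7, with 0 lower in each. The call of Gm5150 ended without mouse 2, 3 or 4 (adjusted p = 0.946, 0.448 and 1.00) without any single DMSO library (adjusted p up to 0.087) and with limma-voom (adjusted p = 0.078), and it passed in 19 of 36 other settings. Without the SR9009 library of mouse 1, 17 genes were higher and 24 lower. Serpinb2 had a double difference of −0.58 (SE 1.92, adjusted p = 0.993), so it was not shown to respond differently to SR9009 with and without LPS. Its level without LPS was near the floor (with SR9009, 0.256 CPM in mouse 2 and 0 in the other libraries). The test could therefore hardly show a difference for Serpinb2. As a list, interferon-stimulated genes had a positive median double difference of 1.37 (camera adjusted p = 7.99e-29, but adjusted p = 0.202 with an estimated correlation; 26 adjusted over the list alone), and plasminogen genes one of −0.31 (camera adjusted p = 0.0379, adjusted p = 0.202 with an estimated correlation; 1 adjusted over the list alone). The plasminogen list did not pass without mouse 3 (adjusted p = 0.121).

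**Figure D4:**
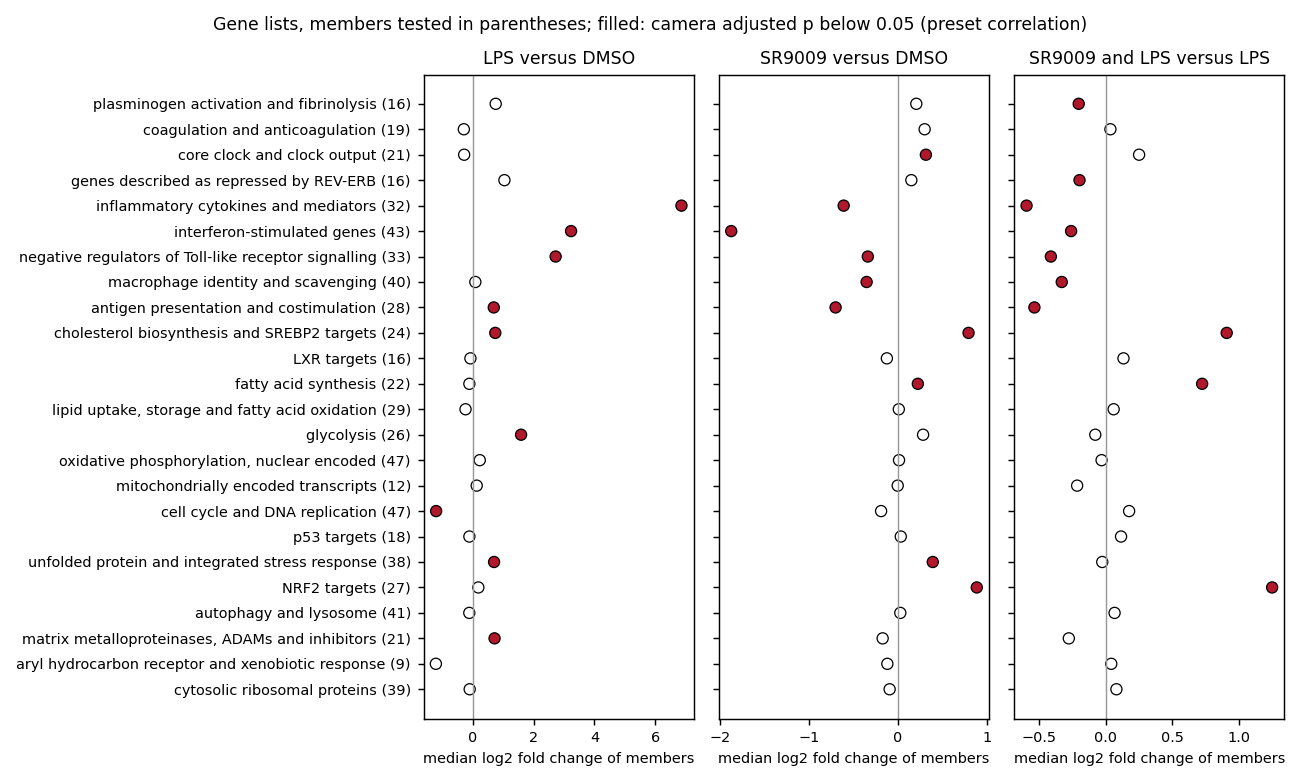
Median log2 fold change of the tested members of each gene list in the 3 main comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes had medians of 3.23 with LPS, −1.87 with SR9009 and −0.26 with SR9009 and LPS against LPS.

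SR9009 effects with and without LPS were set side by side across 13438 genes. The log2 fold changes correlated with Pearson r = 0.317 and Spearman rho = 0.312 across genes, which are not independent replicates. Within single mice, Pearson r ran from 0.142 to 0.351. Of the genes called, 16 were higher in both settings (0.444 by chance if the calls were independent) and 8 lower in both (0.56), and 0 had opposite calls. With the replicate block these counts were 33 and 30, and without the SR9009 library of mouse 1 they were 58 and 48.

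Among 2019 genes raised by LPS by at least 1 on the log2 scale, SR9009 with LPS lowered 86, such as Il1rn and Serpinb2, and raised 3. Among 2222 genes lowered by LPS it raised 98, such as Slc40a1, and lowered 2. Of the first set, 81.6% had a negative SR9009 log2 fold change, against 56.3% in counts simulated with no SR9009 effect, which share the LPS libraries in the same way. Of the second, 86.4% had a positive one, against 59.6%. The simulated genes were drawn independently and without differences between mice. Shifts that many genes of a library share were therefore not simulated, and the simulated shares may be too close to 50%. With LPS-responsive genes taken from 2 mice and the SR9009 effect from the other 2, the shares were 80.0% to 87.3% and 72.8% to 88.2%. The replicate block gave 188 lowered and 198 raised. Leaving out the SR9009 library of mouse 1 gave 430 and 498, and leaving out mouse 4 gave 3 and 1.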

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

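The test of GC content in the SR9009 library of mouse 1 was changed after its first result, and the tests on starting molecules, on the ways to pair the mice and on the interferon-stimulated genes without that library were chosen only after the result was seen. In the SR9009 group, the library of mouse 1 stood apart in 4 measures. It had counts in 13298 genes against 18179 to 18827 in the other 3 libraries, 97.93% of counts in protein-coding genes against 98.69% to 98.72%, 1.064% in pseudogenes against 0.588% to 0.648%, and a mean GC content of 45.94% against 49.92% to 50.17%. The DMSO library of mouse 4 had 97.6% of counts in protein-coding genes against 98.56% to 98.61%. Chance sets a library apart in a share of about 0.05 of groups, and 28 groups of library measures were examined.

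Lower sequencing depth is argued against as the cause in the SR9009 library of mouse 1: thinned to the same total, each of the other 3 libraries kept at least 29.4% more genes with a count. A loss of GC-rich transcripts stays open: the Spearman correlation across genes between GC content and the log2 ratio to the other 3 libraries was −0.712, and GC content went with 43.0% of the variance of that ratio. Few starting molecules also stay open as a candidate explanation, since 32.2% of 363 genes near the median GC content with an expected count of 5 to 20 had no count, against 0.803%, 0.385% and 0.435% in the other 3 libraries. For those 3 libraries, the library of mouse 1 was left out of the expected counts. It was also left out of the GC trends of the other SR9009 libraries. Both explanations may hold together, and no biological explanation was tested.

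Among 17 genes that the report leads with or uses as treatment checks, 68 groups were examined and 5 had a library apart. Arntl was at 36.2 CPM and Nr1d2 at 174.8 CPM in the SR9009 library of mouse 1, against 12.8 to 15.1 and 50.3 to 62.1 CPM in the other 3. Il6 was at 0.110 CPM in the SR9009 library of mouse 2, Plat at 0.201 CPM in that of mouse 3 and Serpinb2 at 0.256 CPM in that of mouse 2, each against 0 in the other 3, which are differences of a few counts. Among 250 other named genes, a library stood apart for 11 in DMSO, 12 in LPS, 38 in SR9009 (30 of them mouse 1) and 10 in SR9009 and LPS, where the share of 0.05 by chance gives 12.5 per group.

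The SR9009 effect differed with and without LPS for Gm5150 (log2 double difference −2.72, edgeR adjusted p = 0.0168) and for 4 lists by camera. The median double difference was −0.31 for plasminogen genes (adjusted p = 0.0379) and 1.37 for interferon-stimulated genes (adjusted p = 7.99e-29). It was −0.53 for the unfolded protein and integrated stress response (adjusted p = 6.11e-06) and 0.0192 for negative regulators of Toll-like receptor signalling (adjusted p = 0.0194 in the negative direction, with a mean of −0.28, so the median differs in sign). None of the 4 lists passed with an estimated correlation (adjusted p = 0.202, 0.202, 0.37 and 0.681). With the replicate block 6 lists passed, these 4 and fatty acid synthesis (median 0.26, adjusted p = 0.0254, against 0.0574 without the block) and mitochondrially encoded transcripts (median −0.19, adjusted p = 0.0381, against 0.112). Without the SR9009 library of mouse 1, a setting chosen after seeing the data, neither of these passed (adjusted p = 0.352 and 0.204) and glycolysis did (adjusted p = 5.64e-06, against 0.102 with it). None of these 3 passed with an estimated correlation, which was also combined with these settings after seeing the data: with the replicate block, fatty acid synthesis and mitochondrially encoded transcripts had adjusted p = 0.543 each, and glycolysis had adjusted p = 0.402 with the block and without that library.

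Interferon-stimulated genes had a median SR9009 effect of −1.87 without LPS and −0.26 with LPS. The SR9009 library of mouse 1 is argued against as the cause, since without it the median double difference was 1.21 times its value with it. A single DMSO library with high levels is argued against, since the SR9009 effect without LPS kept at least 0.847 of its median whichever DMSO library was left out, and so is a loss of GC-rich transcripts, since with the GC content correction the double difference was 1.08 times its value. The size of the difference varied between mouse pairs, in fits chosen after seeing the data: the medians without and with LPS were −2.31 and −0.15 in mice 1 and 2 (double difference 1.83) and −1.42 and −0.48 in mice 3 and 4 (0.964). An SR9009 effect that depends on LPS, the difference the design names, may underlie the pattern. It was found and tested on the same data, and the list did not pass with an estimated correlation.

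Mice 1 and 2 stood apart from mice 3 and 4 across groups: over all 16 libraries, 2159 genes differed between these pairs and 0 in each of the other pairings of mice by edgeR. That fit took the 4 libraries of each mouse as independent, while the contrast rests on 2 mice against 2. The count thus describes the libraries and does not measure spread between animals. GC content bias is argued against, with Spearman correlations no larger in size than −0.105 in the DMSO, LPS and SR9009 and LPS groups. With 1 of 3 pairings giving as many genes, 3 pairings are too few for a share under 0.05. Dendritic cells as a source cannot be told apart from other causes: their marker list had medians of 0.99, 1.65 and 1.00 in these groups (0.990 reached in each, with a median absolute deviation of 0.25 to 0.99), over 3 or 4 members at 1 CPM or more. Its most abundant members were Bst2 (339.5 CPM in DMSO), which is also on the interferon-stimulated list, and Clec10a (13.4 CPM). Ccr7, Batf3 and Zbtb46 reached at most 7.99, 1.98 and 1.74 CPM in any library. The other members stayed below 1 CPM, with Flt3, Xcr1, Clec9a and Siglech at most 0.231, 0.415, 0.357 and 0.385 CPM and Cd209a at 0. Only 3 of the 9 marker lists had enough members for this measure in all 3 groups. No sort is recorded that would remove such cells, and differences between the animals or their culture days were not tested.

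Other splits of the 8 libraries of each comparison were counted. For LPS versus DMSO, 1 of 35 splits, the real one, gave as many genes (5352, highest other 0), and so did SR9009 versus DMSO (1 of 35, 118, highest other 6) and SR9009 and LPS versus SR9009 (1 of 35, 4070, highest other 1345). Chance can be excluded for these 3 only when the mouse number that the libraries share is ignored. For SR9009 and LPS versus LPS, 2 of 35 splits gave as many genes (241, highest other 1522), so chance is not excluded by this count. The higher split set mice 1 and 2 against mice 3 and 4, which points to a structure of the samples, and with the replicate block 296 genes were higher and 239 lower. For the interaction 2 of 35 splits gave as many (1, highest other 61, the same mouse split), and chance is not excluded. The real split parts all 4 pairs of libraries from 1 mouse; among the 8 splits that do so, the highest other was 0, 0, 0, 232 and 0 in the order of the 5 contrasts, and 8 splits are too few for a share under 0.05.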

How the results depend on the processing

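The GC content correction, leaving out the SR9009 library of mouse 1 in the list tests and overlaps or together with other choices, the replicate block with an estimated correlation, and the fits of mouse pairs were chosen after seeing the data; the other settings were planned. Counts below are genes higher and lower. RLE and upper-quartile scaling and the stricter filter kept each count of genes within 1.5 times its value. Without a filter the counts were 23 higher for SR9009 versus DMSO and 87 and 62 for SR9009 and LPS versus LPS. DESeq2 gave 128 and 203, 364 and 342, and 53 and 50 for the interaction, limma-voom 90 higher for SR9009 and LPS versus LPS and 0 lower for the interaction. On log2 FPKM, SR9009 and LPS versus LPS had 236 lower (pseudocount 1), 157 (pseudocount 0.1) and, without a filter, 79 and 196. SR9009 versus DMSO had 17 higher and SR9009 and LPS versus SR9009 1316 lower without a filter. The interaction had 11 and 38, 2 and 8, and 9 and 27. The replicate block gave 69 and 129 for SR9009 versus DMSO, 296 and 239 for SR9009 and LPS versus LPS and 11 and 4 for the interaction, and with the gene length correction 65 and 150, 273 and 311, and 9 and 2. Fits of the compared groups alone gave 3735 and 4115 for LPS versus DMSO and 215 and 271 for SR9009 and LPS versus LPS. Both exceed the main counts of 2611 and 2741, and 142 and 99. SR9009 versus DMSO had 2 and 2 in such fits, and SR9009 and LPS versus SR9009 had 1137 and 976. These lie below the main counts of 42 and 76, and 1944 and 2126. In these fits the spread comes from fewer libraries, which alone cannot account for changes in opposite directions. The comparisons that fell hold the SR9009 group and those that rose do not. The GC content correction gave 72 and 168, 366 and 421, and 7 and 17 for the interaction, and with the replicate block 157 and 322, 690 and 861, 3132 higher for SR9009 and LPS versus SR9009, and 70 and 53. Leaving out the SR9009 library of mouse 1 with the replicate block gave 4017 and 4830, 235 and 351, 1577 and 1323, 3415 and 3430, and 163 and 108 in the order of the 5 contrasts. That library differed from the others of its group by a chi-square per degree of freedom over genes of 413 to 436, against 11 to 68.7 among those. LPS versus DMSO and SR9009 and LPS versus LPS hold no library of that group. There the removal can act only through what the libraries share in the fit: filter, scaling, mouse terms and spread. Mouse terms were not needed, since without them the removal also gave more genes (3658 and 4177, and 912 and 654). In SR9009 and LPS versus LPS with all libraries, RLE and upper-quartile scaling and the stricter filter gave at most 178 and 100. Such changes of scaling and filter are thus argued against as the source there. The spread was not varied alone. Mice 1 and 2 alone gave 1103 and 906, 0 and 0, 0 and 0, 886 and 564, and 0 lower, and mice 3 and 4 alone 4522 and 4737, 1200 and 1545, 2063 and 2077, 4141 and 4134, and 944 and 795. By the same chi-square, libraries of mice 3 and 4 lay closest in the LPS, SR9009, and SR9009 and LPS groups (9.26, 11 and 13.3). Mice 1 and 2 had 20.0, 413 and 34.2, but were closer in DMSO (10.4 against 25.2). The test sets differences against the spread within groups, so closer libraries go with more calls. Other sources of the difference were not tested. Leaving out 1 mouse or library gave 1817 to 3658 and 1689 to 4177 for LPS versus DMSO, 1 to 95 and 0 to 147 for SR9009 versus DMSO, 2 to 912 and 3 to 654 for SR9009 and LPS versus LPS, 1307 to 3103 and 1123 to 2832 for SR9009 and LPS versus SR9009, and 0 to 17 and 0 to 24 for the interaction. Leaving out single libraries other than SR9009 mouse 1 gave 10 to 37 and 25 to 80 for SR9009 versus DMSO and 45 to 127 and 27 to 93 for SR9009 and LPS versus LPS. Of the values of named genes over all settings, 17559 kept their side of the threshold, 805 no longer passed and 569 newly passed. Among the 17559, the sign could turn only where the gene passed in neither fit, as for Arntl above. Another 5 changed sign with a pass in either fit, all with mice 3 and 4 alone: Nr1d1 in LPS versus DMSO (0.72), Itgam (−0.44) and Acod1 (0.77) in SR9009 versus DMSO, and Nr1d2 (−0.37) and Abcb1b (−0.59) in SR9009 and LPS versus LPS. The cause was not tested. Lists kept their call in 1485 cases, 160 no longer passed, 46 newly passed and 1 reversed, the ribosomal list in SR9009 versus DMSO (adjusted p = 0.0322, higher, with the replicate block and without the SR9009 library of mouse 1; the cause was not tested). With an estimated correlation 2, 0, 0, 3 and 0 lists were called in the order of the 5 contrasts, with the replicate block as well 0, 0, 0, 3 and 0, and also without the SR9009 library of mouse 1 0 in each; fry called 16 lists for LPS versus DMSO, 1 for SR9009 versus DMSO and 0 for the interaction. Leaving out 1 mouse gave 7 to 9, 8 to 12, 9 to 11, 8 to 9 and 3 to 6 called lists. The plasminogen list passed in LPS versus DMSO with fry (adjusted p = 1.63e-07), which asks only whether its genes move one way on balance; leaving out 1 mouse gave 0.0576 to 0.104, and 0.179 to 0.717 in SR9009 versus DMSO. In SR9009 and LPS versus LPS it no longer passed with an estimated correlation (0.105; 0.126 with the replicate block as well; 0.222 also without the SR9009 library of mouse 1), without that library (0.125) or without it and with the replicate block (0.0873), and leaving out 1 mouse gave 0.0128 to 0.125. Its interaction no longer passed with an estimated correlation (0.202; 0.194 with the replicate block; 0.21 also without the SR9009 library of mouse 1), without a filter (0.0929) or with fry (0.0833), and leaving out 1 mouse gave 0.0263 to 0.121. The correlation of the SR9009 effects with and without LPS kept its sign, with Pearson 0.267 to 0.341 and Spearman 0.266 to 0.328 when 1 mouse or that library was left out. Genes higher and lower in both were 43 and 44 with DESeq2, 33 and 30 with the replicate block, and 1 to 58 and 0 to 48 with a mouse or that library left out. Of genes raised by LPS, DESeq2 gave 261 lower and 14 higher with SR9009 and LPS, the replicate block 188 and 7, and leaving out a mouse or that library 3 to 430 and 0 to 27; of genes lowered by LPS the numbers higher and lower were 224 and 6, 198 and 6, and 1 to 498 and 0 to 11, with 5 lower when no minimum size was set. With LPS-responsive genes from mice 1 and 2 and the SR9009 effect from mice 3 and 4 the numbers were 524, 84, 327 and 57; in the other 5 assignments of mice all 4 numbers were 0 by edgeR. All of these fits had 2 libraries per group, so that number alone does not account for the difference. Only the first assignment took the SR9009 effect from mice 3 and 4, whose libraries lay closest to each other in every group but DMSO. In those groups, pairs of libraries that mixed the mouse pairs had a chi-square per degree of freedom of 54.3 to 436. A small spread between close libraries thus goes with the calls, and other sources were not tested. The shares of genes with the opposite sign were 77.8% to 85.0% and 83.2% to 88.7% with a mouse or that library left out. Detection was measured only in simulated data, drawn at the real library sizes with the spread fitted to all 16 libraries. The changed genes had a mean of at least 1 CPM. At 13438 genes, 10 of 100 genes changed by 1 on the log2 scale were recovered for SR9009 and LPS versus LPS and 78 of 100 changed by 2. That spread includes the SR9009 library of mouse 1, and depth was not tested apart from it. Neither a single library that stands apart nor differences between mice were simulated, so the limits in the real data may differ.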

Other observations

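The settings without the SR9009 library of mouse 1 and the replicate block together with an estimated correlation were chosen after seeing the data; no other test in this part was chosen after its result was seen. Antigen presentation genes rose with LPS in 12 of 28 cases and fell in 1 (14 and 1 adjusted over the list alone; median log2 0.68, camera adjusted p = 0.00106, adjusted p = 0.495 with an estimated correlation). With SR9009 against DMSO 2 fell (6 adjusted over the list alone; median −0.70, camera adjusted p = 1.25e-05, adjusted p = 0.438 with an estimated correlation). The replicate block called 5 lower and 0 higher there. With SR9009 and LPS against LPS the median was −0.54 (1 lower adjusted over the list alone; camera adjusted p = 0.00173, adjusted p = 0.538 with an estimated correlation). Of 40 macrophage identity and scavenging genes, 12 rose and 7 fell with LPS (12 and 7 adjusted over the list alone; median 0.08, camera adjusted p = 0.388). In the SR9009 comparison 1 rose and 3 fell (1 and 4 adjusted over the list alone; median −0.35, camera adjusted p = 0.00602, adjusted p = 0.438 with an estimated correlation), and in SR9009 and LPS against LPS 3 fell (2 higher and 8 lower adjusted over the list alone; median −0.33, camera adjusted p = 0.00188, adjusted p = 0.335 with an estimated correlation). With the replicate block 1 rose and 5 fell in SR9009 and LPS against LPS.

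Of 38 genes of the unfolded protein and integrated stress response, 17 rose and 2 fell with LPS (17 and 2 adjusted over the list alone; median 0.69, camera adjusted p = 0.00429, adjusted p = 0.495 with an estimated correlation). With SR9009, 1 rose (4 adjusted over the list alone; median 0.39, camera adjusted p = 2.87e-05, adjusted p = 0.404 with an estimated correlation). With SR9009 and LPS against LPS 1 rose (1 adjusted over the list alone; median −0.03, mean 0.17, test direction negative, camera adjusted p = 0.519). Matrix metalloproteinase and ADAM genes rose with LPS in 7 of 21 cases and fell in 1 (7 and 1 adjusted over the list alone; median 0.71, camera adjusted p = 0.0324, adjusted p = 0.395 with an estimated correlation, and adjusted p = 0.176 without the SR9009 library of mouse 1, where the call ended). The list did not pass with SR9009 (median −0.17, camera adjusted p = 0.913) or SR9009 and LPS (median −0.28, camera adjusted p = 0.0762).

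Of 16 genes described as repressed by REV-ERB, 7 rose and 4 fell with LPS (7 and 4 adjusted over the list alone; median 1.04, camera adjusted p = 0.0668) and 2 fell with SR9009 (2 adjusted over the list alone; median 0.15, mean −0.12, test direction negative, camera adjusted p = 0.453). With SR9009 and LPS against LPS the median was −0.20 (2 lower adjusted over the list alone; camera adjusted p = 0.04, adjusted p = 0.329 with an estimated correlation, and adjusted p = 0.167 without the SR9009 library of mouse 1, where the call ended); this list holds Arntl and inflammatory genes side by side. Coagulation genes had 5 higher and 5 lower of 19 with LPS (5 and 5 adjusted over the list alone; median −0.30, mean 0.27, test direction negative, camera adjusted p = 0.941), with medians of 0.30 (camera adjusted p = 0.295) and 0.04 (camera adjusted p = 0.972) in the SR9009 comparisons.

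The other lists did not pass by camera in the 3 main comparisons, given here as LPS, SR9009, and SR9009 with LPS against LPS. LXR targets had medians of −0.08, −0.13 and 0.13 (camera adjusted p = 0.467, 0.851 and 0.333), lipid uptake and oxidation −0.25, 0.01 and 0.06 (0.467, 0.62 and 0.121), nuclear encoded oxidative phosphorylation 0.22, 0.01 and −0.03 (0.164, 0.569 and 0.592), and mitochondrially encoded transcripts 0.12, −0.00 and −0.21 (0.602, 0.62 and 0.178). The p53 targets had −0.12, 0.03 and 0.12 (0.815, 0.453 and 0.793), autophagy and lysosome −0.12, 0.02 and 0.07 (0.815, 0.53 and 0.972), the aryl hydrocarbon receptor list −1.22, −0.12 and 0.04 (0.421, 0.453 and 0.972), and cytosolic ribosomal proteins −0.11, −0.09 and 0.08 (0.633, 0.557 and 0.315). In the SR9009 comparison the median of the LXR list and of the mitochondrial list was negative and the test direction positive, and for p53 targets the test direction was negative. With the replicate block, mitochondrially encoded transcripts passed in SR9009 with LPS against LPS (adjusted p = 0.0384, lower), though not with an estimated correlation as well (0.446) or when the SR9009 library of mouse 1 was left out as well (0.0922). Without that library, autophagy and lysosome (adjusted p = 0.00467, higher) and the aryl hydrocarbon receptor list (0.00892, lower) passed in SR9009 against DMSO, and so they did with the replicate block as well (0.00297 and 0.0126), where the ribosomal list also passed (0.0322, higher). With an estimated correlation added to the block and without that library, none of these 3 lists passed (lowest adjusted p = 0.121, the aryl hydrocarbon receptor list).

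Of the 9 marker lists, those of neutrophils (4 of 14 members tested), B cells (3 of 10), dendritic cells (5 of 12), megakaryocytes (4 of 10) and osteoclasts (8 of 10) could be tested as lists, and none passed by camera in the 5 contrasts; the lowest value was that of megakaryocyte markers with LPS (median −2.64, adjusted p = 0.0598). For LPS the medians of the others were 1.33 (neutrophil), −1.66 (B cell), 0.52 (dendritic cell) and −0.19 (osteoclast). With SR9009 and LPS against LPS they were −0.62 (neutrophil, camera adjusted p = 0.0965, fry adjusted p = 0.0174), −0.15 (B cell), 0.05 (dendritic cell), 1.41 (megakaryocyte) and 0.39 (osteoclast). Csf3r of the neutrophil list fell (1 of 4, and 1 adjusted over the list alone), as did Hdc, the only mast cell marker tested (−2.19, and 1 adjusted over the list alone), and LPS had raised both (2.29 and 7.90). Of the other neutrophil markers, Mmp8, S100a8 and Cebpe reached 50.7, 6.71 and 3.30 CPM, while S100a9 reached 0.237 CPM and Ly6g had 0. No mast cell marker but Hdc exceeded 0.118 CPM in any library. The 2 decreases thus do not show a change in such cells. With SR9009 against DMSO the medians were 0.29 (neutrophil), −0.64 (B cell), −0.77 (dendritic cell), 0.10 (megakaryocyte) and −0.16 (osteoclast). At an unadjusted p under 0.05 in edgeR, Hdc (−2.46) and 1 B cell marker were lower there, and 1 neutrophil and 1 osteoclast marker higher. DESeq2 called Hdc and 1 osteoclast marker, the replicate block 1 B cell marker, and limma-voom 0. With the replicate block and without the SR9009 library of mouse 1 the megakaryocyte list passed by camera (adjusted p = 0.0383, higher), though not with an estimated correlation as well (adjusted p = 0.154). Markers of T and NK cells (1 of 12), erythroid cells (1 of 12), fibroblasts (2 of 14) and mast cells (1 of 11) had too few tested members, with medians of 3.27, −1.10, 0.99 and 7.90 with LPS. Bst2, Mmp8, Mmp9 and Vwf are also on other lists.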
